A study of Vanessa cardui and Junonia coenia with 16 samples.

How the data were processed

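The series holds 16 labelled RNA-seq libraries, 8 from each of 2 butterfly species. Per the labels' protocols, animals were reared at 27 °C, RNA was isolated from dissected forewings or hindwings, poly(A) RNA was selected, libraries were amplified with 15 PCR cycles, and paired-end reads of 36 bp were sequenced. The labels describe the libraries of a group as biological replicates. They do not say whether a forewing and a hindwing library of one number came from the same animal, except for the asymmetric V. cardui wings, which came from 1 individual.

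The deposited tables hold FPKM values per assembly row and library, computed by the authors. Per the submitters' processing notes, Bowtie2 was used. The J. coenia row identifiers carry the prefix of the Trinity assembler. The versions of both programs, the quantification program, the assembly program behind the V. cardui rows, any annotation and any scaling between libraries are not given in the sources used here. FPKM divides by transcript length and by the total of the library, so a few very abundant transcripts change the values of all others, and an exact 0 can be a failed estimate. Per the file headers, 2 columns of the V. cardui table match no labelled sample, and these were not used. Their names have the form of V. cardui wild-type hindwing libraries, but none of the labels names them. Row identifiers were looked up in the reference table of 15000 V. cardui genes (assembly ilVanCard2.1), and 0 matched in either species. Names are therefore not used. The rule fixed for that case, to name at most 2 rows that rose and 2 that fell per comparison, was applied to the largest log2 changes among called rows whose groups did not overlap. Where fewer were called, rows with an unadjusted p under 0.01 were taken and are said not to be called. For the asymmetric pair the largest differences among rows with at least 10 FPKM in a wing were named. The 16 gene lists fixed in advance, the tests on them and the comparison of effects between the species need names and were not run.

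The number of reads per library is not known from FPKM. Relative depth was recovered from low values: rows with values under 0.6 FPKM in both of 2 libraries gave a peak of the ratio of what 1 read is worth, and the peaks of all 28 pairs per species were fitted jointly by least absolute deviations. All 28 J. coenia pairs lay within 0.04 (log2) of the fit, and 27 of 28 V. cardui pairs within 0.03. The remaining pair, wild-type forewing 1 with knockout forewing 1, the deepest and the shallowest V. cardui library by the fit, was off by 1.01, for a cause that was not tested. Its own peak, at -0.6 (log2), would put these 2 libraries closer in depth. These values order the libraries of a species by depth and give no counting interval, so precision is taken from replicates.

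Tests used limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), so log2 changes are on that scale and understate changes of low rows. Within each species a group-means model was fitted to the melanin-stage libraries, 6 in V. cardui and 8 in J. coenia, with empirical Bayes moderation and a mean-variance trend. Rows with a mean of at least 1 FPKM over the libraries of the fit were tested (19184 in V. cardui and 28183 in J. coenia). P-values are two-sided, adjusted by the Benjamini-Hochberg method, and called at an adjusted p of 0.05. A fold is not given against a group listed at 0. The asymmetric pair has 1 library per wing and is described by differences of log2(FPKM + 1), and the medians of called rows were ranked among 10000 random lists matched on mean expression in 20 classes. The groups, the model, the filter, the naming rule and the alternatives listed next were fixed before the data were examined. These alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, the replicate number as a block, a fit of only the compared groups, moderation without trend, and leaving out each library.

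Pairing by number was checked as the correlation, across rows, of replicate 1 minus replicate 2 between groups. In V. cardui it was 0.02, -0.03 and -0.10. In J. coenia it was 0.58 between wild-type forewings and hindwings and 0.60 between knockout forewings and hindwings (0.91 and 0.88 at a mean of at least 20 FPKM). Between genotypes it was 0.14 to 0.24 (0.23 to 0.40 at a mean of at least 20 FPKM). With 2 libraries per group these are only 2 independent values for the wings, and the labels are silent, so the main fits keep the libraries separate. Alternatives that take genotype and number as a correlated or a fixed block, or average such wings, were added after the data were seen and are printed beside the mean of both wings, the interaction and the wild-type wing comparison, and otherwise only with the other alternatives. Also added were sums of FPKM over all rows, tested or not, that share an assembly component. A component is the c number of a V. cardui identifier and the DN number of a J. coenia identifier. A fit without both J. coenia wild-type libraries numbered 2 was added too, as these correlated least with the libraries other than each other. A J. coenia sum pools every c number under its DN number, so it is a wider unit than in V. cardui and may join separate clusters. Sums per DN and c number were not fitted, and counts per component are not alike between the species.

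The fits were tested on simulated log2 values with the means and moderated spread of the real rows and 200 changed rows. For the V. cardui forewing comparison (19184 rows), 0%, 10.4% and 50% of rows with true log2 changes of 1, 2 and 4 were called, with 0 false calls. For the J. coenia forewing (28183 rows) the shares were 0%, 0% and 1.5%, with 0 false calls. For the mean of both J. coenia wings they were 0%, 6% and 60.6%, with 4 false calls. These simulations had no correlation between wings, against an estimate of 0.645 in J. coenia. Their noise was normal, so no group was listed at 0 in all its libraries, as many called rows are. The shares and false calls therefore need not hold for the real rows. With no changed rows and a simulated correlation of 0.6 between wings, the mean of both wings gave 0 calls and 11.8% of rows at an unadjusted p under 0.05, against 4.9% without that correlation and 16.6% in the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.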

Results

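RNA was sequenced from developing wings of 2 butterflies, the painted lady Vanessa cardui and the common buckeye Junonia coenia. Each wing was wild type or labelled as a knockout of optix, a transcription factor gene known for its role in wing colour patterning. Wings were collected late in pupal life, when the orange to red ommochromes and the dark melanins appear, and the series title frames the comparison around colour and iridescence. For V. cardui there were 2 wild-type forewing libraries, 2 knockout forewing libraries and 2 knockout hindwing libraries, all from the stage the labels name for melanin. A further pair of V. cardui forewings came from 1 mosaic knockout individual at the stage named for ommochromes, 1 wing with large defects and 1 with very small ones. For J. coenia there were 2 libraries each of wild-type forewing, knockout forewing, wild-type hindwing and knockout hindwing at the melanin stage. The knockout forewings of both species and the V. cardui knockout hindwings are labelled as having large defects, and the J. coenia knockout hindwings simply as knockouts. The share of knockout cells in these wings was not measured.

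The values were FPKM (fragments scaled to transcript length and to the total mapped per library) for rows of a transcriptome assembly. Of 74995 V. cardui rows, 41660 were above 0 in a labelled library, and of 182199 J. coenia rows, 74480 were. The row identifiers carry no gene names and 0 of them matched the reference gene table, so optix itself is not analysed here and the genotype of each library rests on its label. For the same reason pigment genes, markers of other cell types and the correspondence of rows between the species are not analysed here, and changes are described by row.

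Depth and composition went with genotype, in opposite directions in the 2 species. The depths are estimates from low values, and 1 V. cardui pair, wild-type forewing 1 with knockout forewing 1, departed from them by 1.01 (log2). Relative to the shallowest library of its species, sequencing depth in V. cardui was 3.05 and 2.13 in the wild-type forewings, 1.0 and 1.95 in the knockout forewings, and 1.93 and 1.83 in the knockout hindwings. In J. coenia the wild types were the shallower libraries, at 1.37 and 1.0 in the forewing and 1.27 and 1.58 in the hindwing, against 2.11 and 2.86 in the knockout forewings and 2.71 and 3.3 in the knockout hindwings. The 10 most abundant rows held 27.1% ± 0.75 (SD, n = 2) of total FPKM in V. cardui wild-type forewings and 36.5% ± 2.62 (SD, n = 2) in knockout forewings. In J. coenia forewings the order was the other way round, with 39.9% ± 3.69 (SD, n = 2) in wild type and 33.4% ± 0.88 (SD, n = 2) in knockouts. In J. coenia hindwings the shares were 37.4% ± 0.51 (SD, n = 2) and 30.9% ± 2.64 (SD, n = 2).

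V. cardui libraries correlated with their replicates at 0.87 to 0.89 (Pearson's r of log2(FPKM + 1) across 19184 rows, which are not independent replicates). In J. coenia the replicates of a group were less alike than the wings of one genotype and number. The wild-type forewings correlated at 0.60 with each other, while wild-type forewing 1 and hindwing 1 correlated at 0.83, and so did wild-type forewing 2 and hindwing 2. The knockout forewings correlated at 0.81 with each other, and knockout forewing 1 and hindwing 1 at 0.92.

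**Figure D1:**
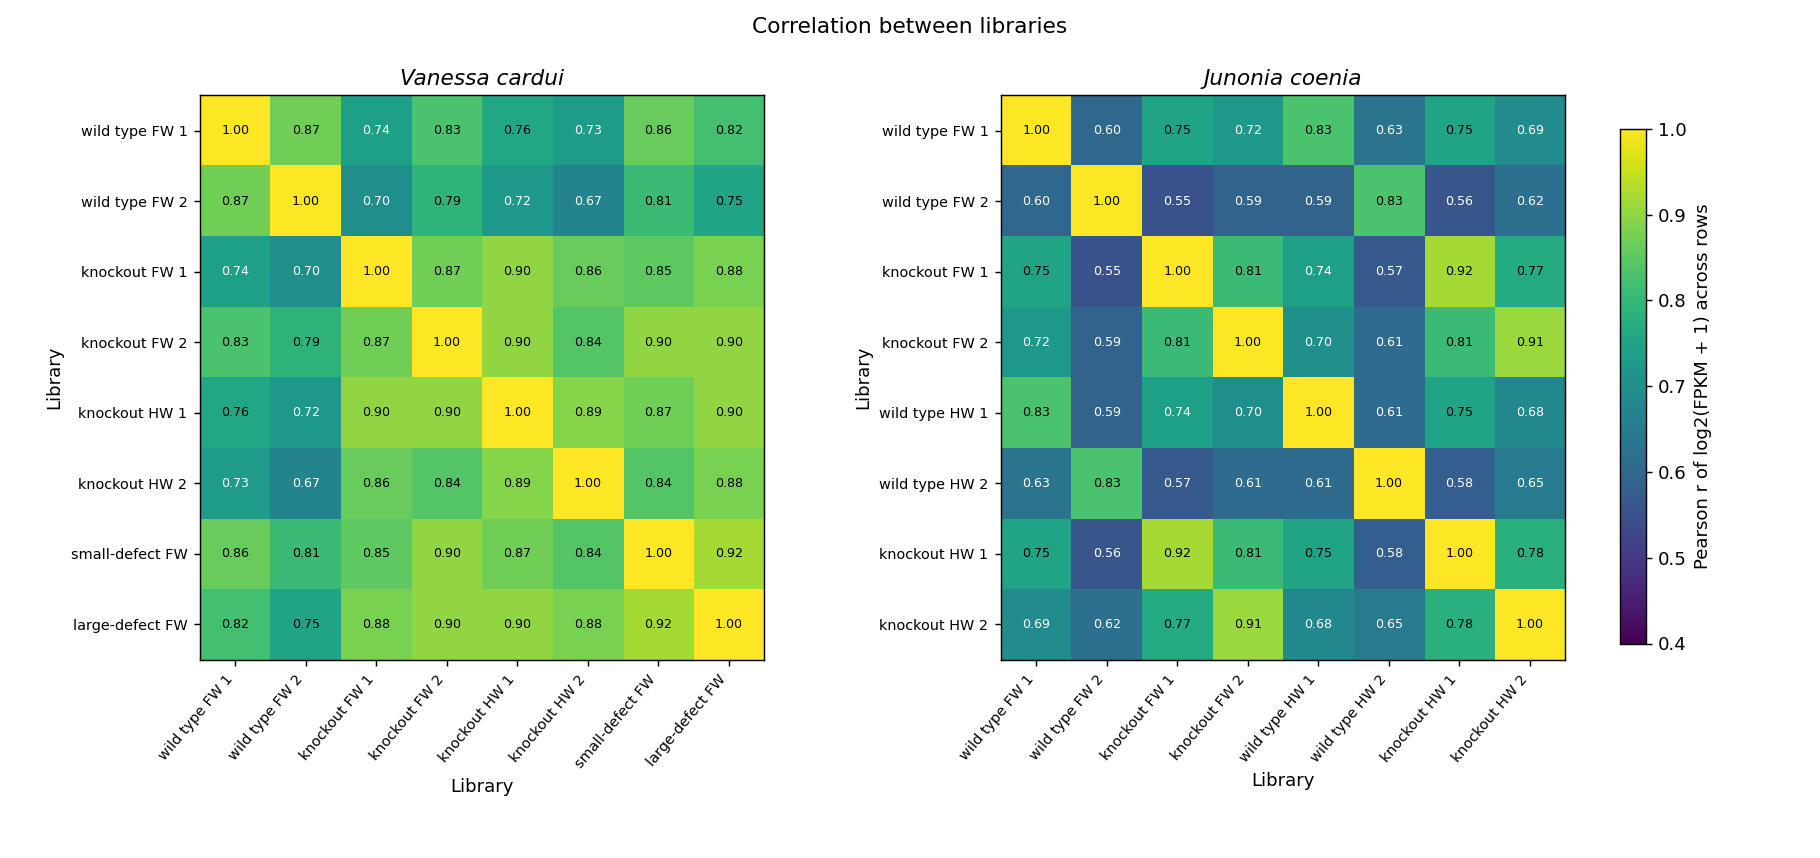
Pearson correlation of log2(FPKM + 1) between each pair of libraries, for V. cardui (left, 19184 rows) and J. coenia (right, 28183 rows), with FW for forewing and HW for hindwing and each value printed in its cell. In J. coenia the wings that share a genotype and a number correlate at 0.83 to 0.92, above the 0.60 to 0.81 between replicates of one group.

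The V. cardui forewing comparison asks which transcripts differ in abundance between wings labelled as optix knockouts and wild-type wings. The row that fell most was c16935_g1, among the most abundant transcripts of the wild-type forewing (rank 4 and rank 8 in the 2 libraries). It was at 22926 and 15566 FPKM in wild-type forewings and at 40.1 and 33.4 FPKM in knockout forewings, a change of -8.97 on the log2(FPKM + 1) scale (SE 0.31, adjusted p = 0.0096, limma). It was also low in the knockout hindwings, at 48.1 and 70.0 FPKM. The row c27787_g2 was at 62.9 and 38.4 FPKM in wild type and listed at 0 in both knockout forewings (adjusted p = 0.0475, limma). The sum over its component, which has 7 tested rows, changed by -1.44 (log2) and was not called (adjusted p = 0.119, limma). Among rises, c26251_g5 went from 2.47 and 1.18 FPKM to 59.9 and 51.7 FPKM (log2 change 4.36, SE 0.46, adjusted p = 0.0475, limma), and c6929_g1 was listed at 0 in both wild types and at 23.3 and 16.5 FPKM in the knockouts (adjusted p = 0.0475, limma). The sum over the component of c26251_g5, which has 7 tested rows, rose by 1.565 (log2) and was not called (adjusted p = 0.117, limma). The component of c6929_g1, its only tested row, was not called either (adjusted p = 0.0542, limma).

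In all, 82 of 19184 rows were called, 28 higher and 54 lower in the knockout. Of the 54 that were lower, 42 were listed at 0 in both knockout forewings, and of the 28 that were higher, 8 were listed at 0 in both wild types. At an unadjusted p under 0.05 there were 4527 rows against 959 expected with no effect, 1619 higher and 2908 lower. The row c16935_g1 was the 1 row called with a pseudocount of 0.1, without the filter on low values or with a mean of at least 5 FPKM, and its component was the 1 component called when rows were summed per assembly component. A fit of the 4 forewing libraries alone called 0 rows (limma, 4701 at an unadjusted p under 0.05; c16935_g1 at adjusted p = 0.0679). Without knockout forewing 1 or knockout forewing 2 no row was called by limma (2699 and 4908 at an unadjusted p under 0.05), and without wild-type forewing 1 or 2 there were 573 and 502 calls.

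**Figure D2:**
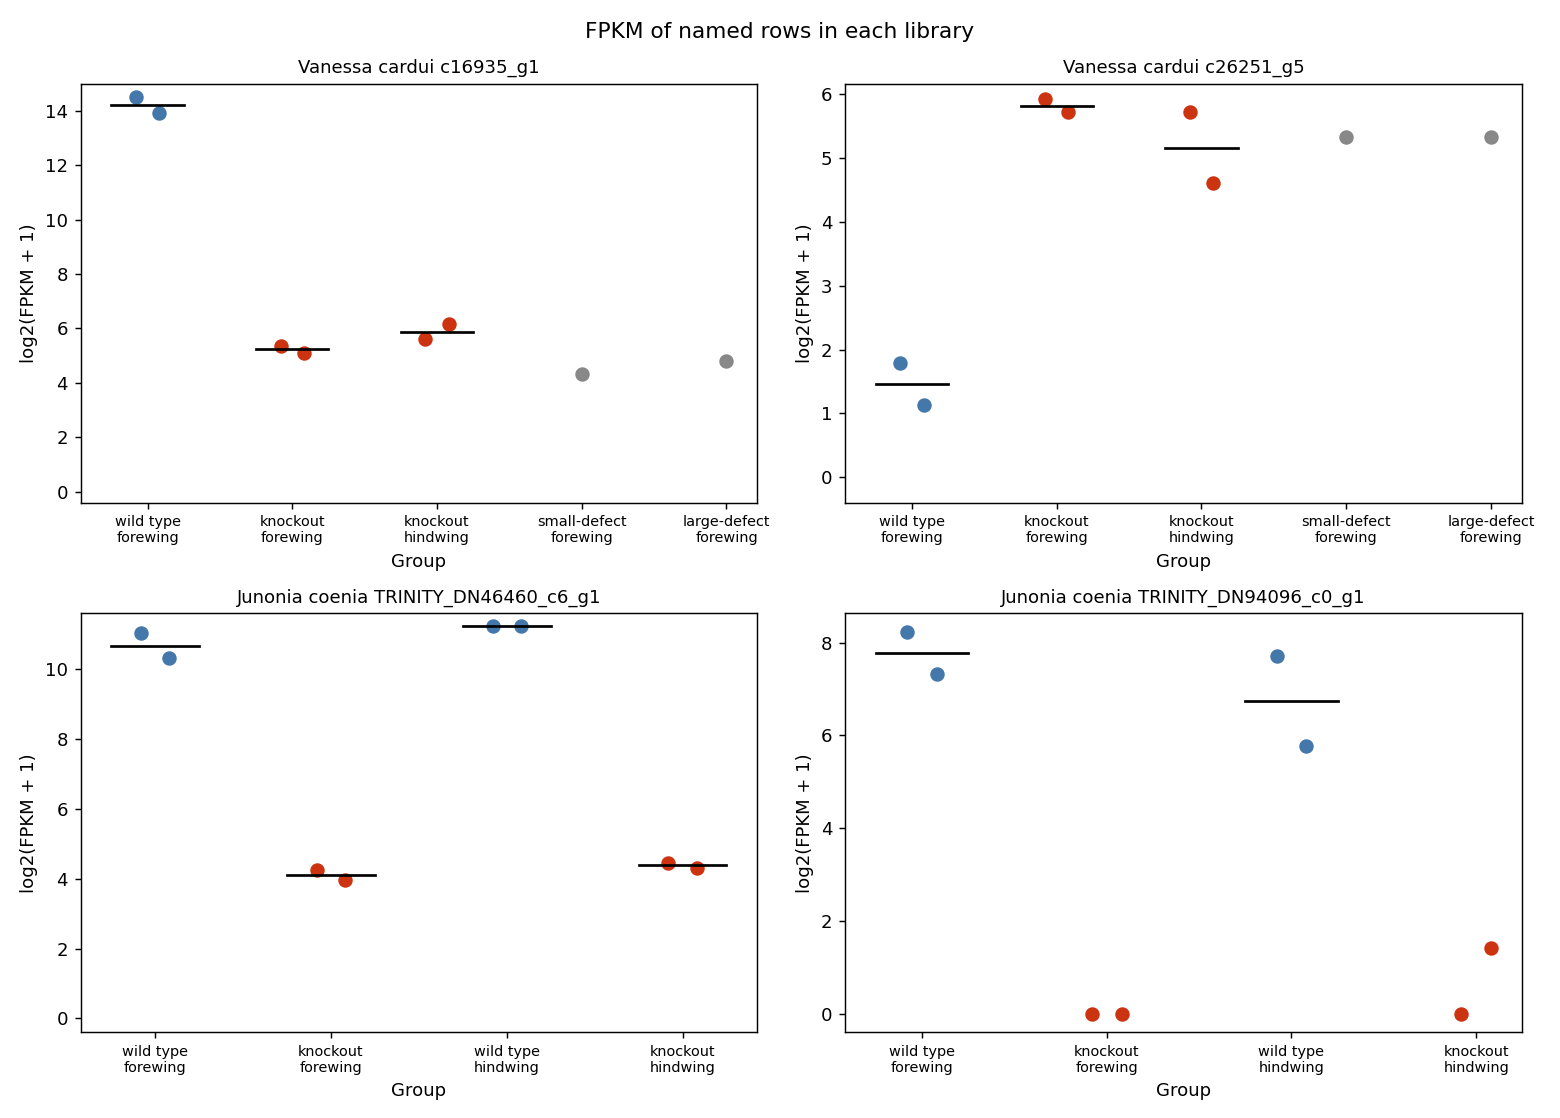
log2(FPKM + 1) of 2 V. cardui rows (top) and 2 J. coenia rows (bottom) in each library, with a point for each library, blue for wild type, red for knockout and grey for the wings of the mosaic individual, and a black bar for the mean of 2 libraries that are both above 0. The wild-type libraries stand apart from the knockouts in all 4 rows. Both wings of the mosaic individual lie with the knockouts for c16935_g1 and c26251_g5. They do not for c27787_g2 (not drawn), at 45.8 and 35.6 FPKM in these wings and listed at 0 in the 4 knockouts. The mosaic wings are from the ommochrome stage, which has no wild-type library, so stage and genotype cannot be told apart in them.

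The J. coenia forewing comparison puts the same question to the second species. The row TRINITY_DN94096_c0_g1 was at 297 and 160 FPKM in wild-type forewings and listed at 0 in both knockouts (adjusted p = 0.019, limma). It is the only tested row of its assembly component, which was also called (adjusted p = 0.0304). TRINITY_DN41136_c1_g1 was at 190 and 161 FPKM in wild type and listed at 0 in the knockouts. However, the sum over its component, which has 2 tested rows, changed by -0.90 (log2) and was not called (adjusted p = 0.641, limma). The 2 called rows that rose most, TRINITY_DN40268_c0_g3 and TRINITY_DN39731_c1_g1, were listed at 0 in wild-type forewings. They reached 230 and 183 FPKM and 164 and 170 FPKM in the knockout forewings. The sums over their components changed by -0.71 and 0.11 (log2), and neither was called.

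Of 28183 rows, 148 were called in the J. coenia forewing, 90 higher and 58 lower, and 2748 had an unadjusted p under 0.05 against 1409 expected. Of the rows called higher, 73 were listed at 0 in both wild types, and of those called lower, 35 were listed at 0 in both knockouts. Summing rows per assembly component left 18 calls among 11368 components, 3 higher and 15 lower. Leaving out any 1 of the 4 forewing libraries ended every call (0 rows by limma each time, with 1736 to 4406 at an unadjusted p under 0.05), and so did fitting the forewings alone (2364). The median row was 0.18 (log2) higher in the knockouts, a shift that quantile normalization moved by -0.16, so the called changes stand against a general offset of that size. In V. cardui the median row was at -0.09 (log2, knockout minus wild type), and the same normalization moved it by 0.20, so its sign depends on the normalization.

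In the J. coenia hindwing, TRINITY_DN46460_c6_g1 fell from 2404 and 2417 FPKM in wild type to 21.0 and 18.7 FPKM in the knockouts (log2 change -6.85, SE 0.39, adjusted p = 0.00408, limma). The sum over its component, which has 4 tested rows, also fell, by 4.82 on the log2 scale (adjusted p = 0.0133, limma). In the forewing the same row was at 2111 and 1269 FPKM in wild type and at 18.0 and 14.7 FPKM in the knockouts (log2 change -6.56, SE 0.39, adjusted p = 0.00451, limma). TRINITY_DN41136_c1_g1 fell in the hindwing as well, from 219 and 190 FPKM to 0 and 1.71 FPKM, with a component change of -0.98 that was not called. The called rises were again led by TRINITY_DN39731_c1_g1 and TRINITY_DN40268_c0_g3, listed at 0 in wild-type hindwings and at 200 and 252 FPKM and 242 and 173 FPKM in the knockouts.

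There were 128 calls in the hindwing, 75 higher and 53 lower, and 2540 rows at an unadjusted p under 0.05. Of these calls, 65 of the higher and 45 of the lower were also called in the forewing, against 0.24 and 0.11 expected for independent lists. These lists are not independent, since wings of one genotype and number deviate together, and the overlap to be had without a knockout effect was not estimated. The effects in the 2 wings correlated at 0.66 across rows (covariance 0.79), but dividing the same libraries by number instead of genotype gave 0.65 (covariance 0.73), and setting wild type 1 and knockout 2 against the rest gave 0.49 (covariance 0.40), so this correlation also reflects what wings of one genotype and number share. Per component 13 were called in the hindwing, all lower, and leaving out any 1 hindwing library ended every call (0 rows by limma, with 1687 to 3003 at an unadjusted p under 0.05), as did fitting the hindwings alone (2267).

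**Figure D3:**
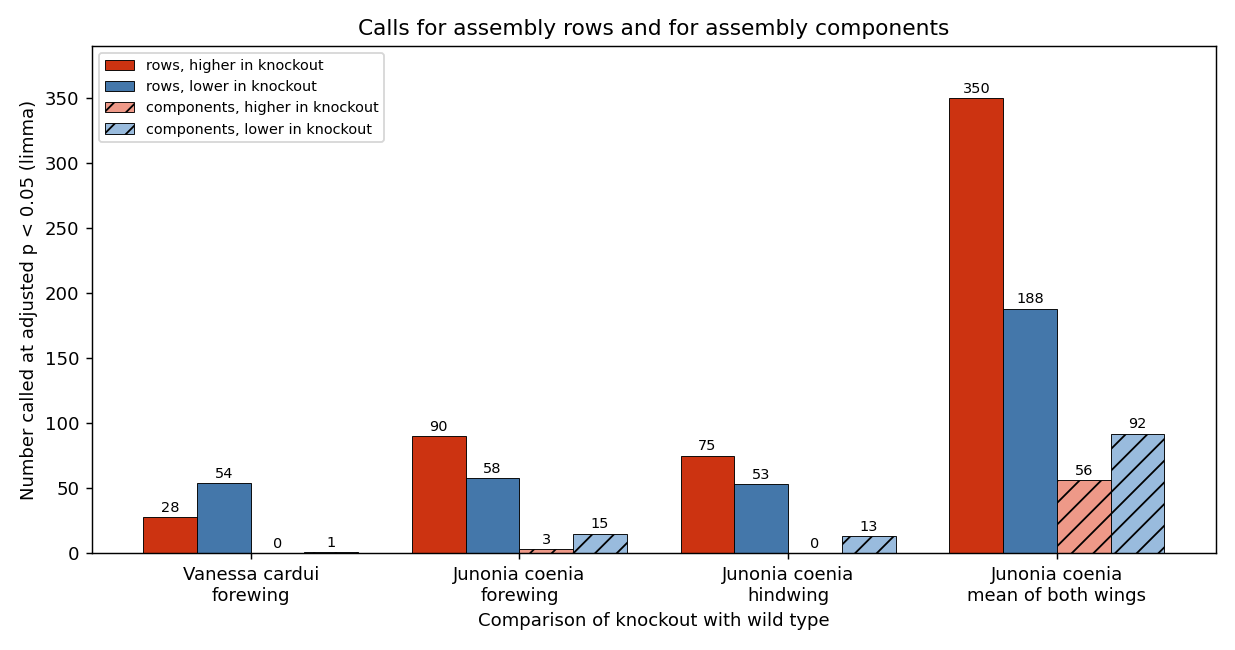
Number of rows (solid bars) and of assembly components (hatched bars) called higher (red) or lower (blue) in knockouts than in wild types, by limma at an adjusted p threshold of 0.05. A component is a c number in V. cardui and a DN number, with all its c numbers, in J. coenia. Rows called higher outnumber rows called lower in J. coenia (350 against 188 for the mean of both wings), and components do the opposite (56 against 92). These counts treat wings of one genotype and number as independent. With correlated wings fewer rows were called for the mean of both wings, and with averaged wings none. Components were not fitted in these ways.

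Averaged over both wings of J. coenia, the knockout effect was largest for TRINITY_DN50972_c26_g1 among rows that rose. It was at 1705 and 1456 FPKM in knockout forewings and 1780 and 1189 FPKM in knockout hindwings. The wild-type libraries numbered 1 held 31.6 FPKM in the forewing and 19.9 FPKM in the hindwing, and those numbered 2 held 0.35 and 0 FPKM. The log2 change was 8.10 (SE 1.27, adjusted p = 0.0365, limma), and the sum over its component rose by 4.04 (adjusted p = 0.013). The row was not called with the estimated correlation between wings (adjusted p = 0.0745) or without any 1 of the 8 libraries (adjusted p from 0.0509 to 0.161). Among rows that fell, TRINITY_DN94096_c0_g1 was at 210 and 53.4 FPKM in wild-type hindwings and at 0 and 1.68 FPKM in knockout hindwings, besides the forewing values above, and its component was called (adjusted p = 0.00546, limma). The other 2 rows named by the rule, TRINITY_DN40268_c0_g3 and TRINITY_DN41136_c1_g1, were called as rows and not as components (adjusted p = 0.269 and 0.24).

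Over both wings 538 rows were called, 350 higher and 188 lower, and 4687 had an unadjusted p under 0.05. Of the rows called higher, 210 were listed at 0 in all 4 wild types, and of those called lower, 65 were listed at 0 in all 4 knockouts. Per component 148 were called, 56 higher and 92 lower. This fit treats the wings of one genotype and number as independent: with their estimated correlation of 0.645 it called 133 rows, 78 higher and 55 lower, and with each such pair of wings averaged it called 0 (limma, 2315 rows at an unadjusted p under 0.05). Leaving out 1 library at a time gave 111 calls (without knockout forewing 1) to 287 calls (without wild-type forewing 1).

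Whether the knockout effect differed between the wings of J. coenia was tested as an interaction. No row passed (limma, 0 of 28183, smallest adjusted p = 0.299). At an unadjusted p under 0.05 there were 533 rows, fewer than the 1409 expected with no effect. The lack of calls therefore does not show that the effect was equal in the wings. With the estimated correlation between wings 2 rows passed, 1 in each direction, and with genotype and number as a fixed block none did (1448 at an unadjusted p under 0.05). Without both wild-type libraries numbered 2, which leaves 1 wild-type library per wing, 272 rows passed, 112 higher and 160 lower.

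Wild-type hindwings and forewings of J. coenia were compared to describe the difference between the wings without the knockout. The row nearest to the threshold was TRINITY_DN40268_c0_g1, listed at 0 in both forewings and at 62.2 and 53.5 FPKM in the hindwings (adjusted p = 0.068, limma). TRINITY_DN51701_c6_g1 was listed at 0 in the forewings and at 94.9 and 9.66 FPKM in the hindwings. TRINITY_DN35396_c0_g1 (69.0 and 10.1 FPKM) and TRINITY_DN42140_c0_g2 (53.7 and 7.60 FPKM) were above 0 in the forewings and listed at 0 in the hindwings. None of these was called, and their component sums changed by -0.10, 0.27, 0.65 and -0.99 (log2, hindwing minus forewing). In all 0 of 28183 rows passed by limma, with 907 at an unadjusted p under 0.05, fewer than the 1409 expected with no effect. With the estimated correlation between wings 74 rows passed, 41 higher and 33 lower in the hindwing, and 34 of the 74 moved the same way between the knockout wings. The rest did not all move the other way: some, such as TRINITY_DN40268_c0_g1 and TRINITY_DN35419_c0_g1, were listed at 0 in every knockout library. With genotype and number as a fixed block 0 passed (2114 at an unadjusted p under 0.05), and without both wild-type libraries numbered 2, which leaves 1 library against 1, 266 did.

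Between the knockout hindwings and forewings of V. cardui no row was called either (limma, 0 of 19184, smallest adjusted p = 0.203, 1235 at an unadjusted p under 0.05). Rows at an unadjusted p under 0.05 were higher in the hindwing in 422 cases and lower in 813. The rows with the largest separated differences were c61670_g1, listed at 0 in the forewings and at 16.5 and 15.4 FPKM in the hindwings, and c62707_g1, listed at 0 in the forewings and at 50.3 and 8.55 FPKM in the hindwings. In the other direction c20176_g2 was at 33.8 and 22.6 FPKM in the forewings and c34971_g1 at 9.53 and 26.7 FPKM, and both were listed at 0 in the hindwings. V. cardui wild-type hindwings are not analysed here, so no knockout effect was computed for that wing.

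The asymmetric V. cardui individual gives a comparison of wings within 1 animal, with 1 library for each wing and hence no replicate check. Rows that were lower in the knockout forewings tended to be lower in the wing with large defects than in the wing with small ones. Of the 54 rows called lower, 39 were lower in the large-defect wing, 9 were listed at 0 in both wings, and the median difference was -0.86 (log2), below the central range of -0.29 to 0.03 that 95% of 10000 random lists of equal size and expression gave. Of the 28 called higher, 16 were higher in the large-defect wing, and their median difference of 0.04 stood at percentile 90.3 of such lists. The row c16935_g1 was at 19.0 FPKM in the small-defect and 27.0 FPKM in the large-defect wing, and c26251_g5 at 39.2 and 39.5 FPKM, so both wings were closer to the knockout than to the wild-type forewings for these rows. The row c27787_g2 went the other way, at 45.8 and 35.6 FPKM in the mosaic wings and listed at 0 in all 4 knockout libraries, and c6929_g1 lay between the groups, at 5.43 and 6.89 FPKM. These wings came from another stage than those of the knockout comparison, and no wild type of that stage is among the libraries. Whether both wings lie near the knockouts by stage or by genotype therefore cannot be told apart. The wing with large defects was the shallower library (1.89 against 2.27). Its 10 most abundant rows held 39.4% of total FPKM, against 35.8% in the small-defect wing, a difference in the same direction as between knockout and wild-type forewings.

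Across 19184 rows the difference between the mosaic wings correlated with the knockout effect at 0.29, and at 0.48 across the 3465 rows with a mean of at least 20 FPKM (rows are not independent replicates). Among the 4527 rows with an unadjusted p under 0.05 in the knockout comparison, 3262 (72.1%) had the same sign in the pair. Across these rows the slope of the pair difference on the knockout effect was 0.19. Choosing rows by a small p in the knockout comparison overstates their knockout effect. The slope therefore does not measure how much smaller the difference was in the pair. The median of all tested rows was -0.07 (log2, large minus small). The rows with the largest differences at 10 FPKM or more in a wing were c13059_g1 (414 FPKM in the small-defect wing and listed at 0 in the large-defect wing) and c42563_g1 (997 and 4.68 FPKM), and in the other direction c60402_g1 and c28747_g7, listed at 0 in the small-defect wing and at 22.4 and 20 FPKM in the large-defect wing. In the knockout comparison c42563_g1 was at 637 and 298 FPKM in wild-type forewings and at 50.7 and 2.35 FPKM in knockout forewings. The other 3 rows showed no such separation there: c13059_g1 was at 4.40 and 0 FPKM in wild type and 3.97 and 0 FPKM in knockouts, c28747_g7 was listed at 0 in all 4 forewings, and c60402_g1 was above 0 in 1 knockout forewing alone (8.76 FPKM).

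**Figure D4:**
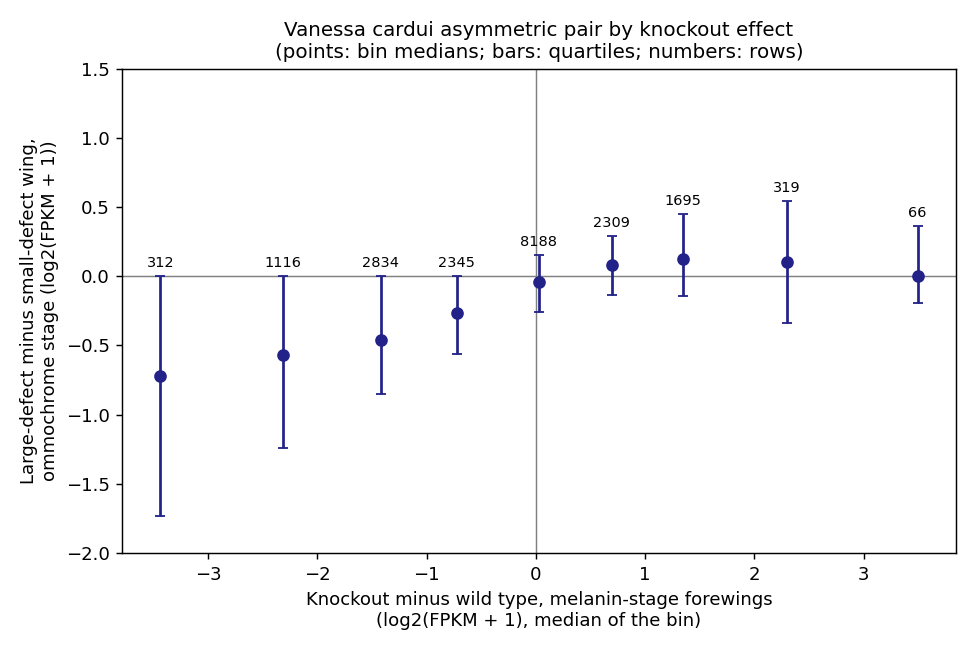
Difference between the large-defect and the small-defect wing of the mosaic V. cardui individual (vertical axis, log2(FPKM + 1)) for rows binned by knockout minus wild type in melanin-stage forewings (horizontal axis, log2(FPKM + 1)), with points at bin medians, bars from the lower to the upper quartile and the number of rows above each bar. The median difference is -0.72 for the 312 rows that were lowest in the knockouts, -0.04 for the 8188 rows nearest to no change and 0 for the 66 rows that were highest in the knockouts, with 0.08 to 0.12 in the bins between.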

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

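The test behind both results here, a fit with correlated wings, was chosen after the data were seen. Each is a J. coenia row whose knockout effect differed between hindwing and forewing in that fit, and both were picked after their values were seen. Groups held 2 libraries, and single libraries were not tested as outliers.

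For TRINITY_DN48010_c0_g4 the hindwing effect minus the forewing effect was 6.33 on the log2(FPKM + 1) scale (SE 0.40, adjusted p = 0.0208, limma with correlated wings). It was at 13.0 and 8.30 FPKM in wild-type forewings and at 5.48 and 6.59 FPKM in knockout hindwings, and listed at 0 in the other 4 libraries. For TRINITY_DN40268_c0_g1 the value was -5.88 (SE 0.37, adjusted p = 0.0208, limma with correlated wings). It was at 62.2 and 53.5 FPKM in wild-type hindwings and listed at 0 in the other 6 libraries. The sizes of both differences depend on the pseudocount, because groups listed at 0 enter them, so neither is a fold. Without that correlation neither row passed (adjusted p = 0.299 for each, limma), and with genotype and number as a fixed block no row did (0 of 28183, limma, 1448 at an unadjusted p under 0.05). Their components have 5 and 3 tested rows. In the fit without correlation, the interaction of the component sums was 1.41 and 0.10 (adjusted p = 1.0 for each, limma). Component sums were not fitted with correlated wings.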

How the results depend on the processing

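The fits per assembly component, with correlated, averaged or blocked wings, and without both J. coenia wild-type libraries numbered 2 were chosen after the data were seen. Counts are rows called by limma, and the cause of each change was not tested, except that leaving out a library or fitting only the compared groups lowers the residual degrees of freedom. A lone library left in a group is assumed to vary like the other groups.

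For the V. cardui forewing (82 calls), median-of-ratios scaling gave 96 calls and quantile normalization 119. A pseudocount of 0.1, no filter, a mean of at least 5 FPKM and component sums each gave 1. The replicate block gave 0 (4010 at an unadjusted p under 0.05) and a fit of only the compared groups gave 0 (4701). Moderation without trend gave 422 calls, 73 higher and 349 lower. Leaving out 1 library gave 0 to 573 calls. The row c16935_g1 kept its direction throughout, and its adjusted p ranged from 0.00342 to 0.178, with 0.0841 under the replicate block. The median difference in the mosaic pair for rows called lower was -0.99 with a pseudocount of 0.1 and -0.77 with median-of-ratios scaling. For rows called higher it was 0.04 and 0.13, and the correlation with the knockout effect was 0.24 and 0.30. The mosaic pair is itself a difference within 1 individual, and no paired analysis was possible as a test because each wing has 1 library.

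For J. coenia the forewing, hindwing and mean of both wings gave 60, 47 and 252 calls without a filter, and 74, 77 and 303 with a mean of at least 5 FPKM. Component sums gave 18, 13 and 148, and the fit without both wild-type libraries numbered 2 gave 394, 473 and 811. Only the compared groups gave 0 in the forewing (2364 at an unadjusted p under 0.05) and 0 in the hindwing (2267). Leaving out 1 library gave 0 to 0 calls in each wing and 111 to 287 in their mean. The mean of both wings also had 821 calls with a pseudocount of 0.1, 133 with correlated wings (103 and 97 in the single wings) and 0 with wings averaged (2315 at an unadjusted p under 0.05). The replicate block, taken as a shared number only, gave 161, 144 and 997 calls. The interaction had 2 calls with correlated wings and 272 without the wild-type libraries numbered 2. The wing difference in wild type had 74 and 266. Under every alternative fixed in advance, the replicate block included, the interaction, this test and the wing test in V. cardui called 0 rows (limma, with 107 to 1732, 206 to 1947 and 657 to 2351 rows at an unadjusted p under 0.05).

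Component sums are not among the alternatives counted here. Their sign was opposite to that of the row for TRINITY_DN40268_c0_g3 (-0.71 in the forewing, -0.61 in the hindwing and -0.66 in their mean). In the wild-type wing comparison it was opposite for TRINITY_DN40268_c0_g1 (-0.10) and TRINITY_DN35396_c0_g1 (0.65). Under the other alternatives the 24 single results behind the named rows never changed sign. Of the 16 called ones, 144 alternative values kept the call and 88 lost it, 52 of these when 1 library was left out. Of the 8 not called, 3 values passed the threshold. With unknown read numbers, how many reads a value of 0 excludes is unknown for rows listed at 0.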

Other observations

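Tests chosen after the result was seen were those on opposite-moving rows of a component, on rows found in the shallower wild types, and on differences between libraries of one group. The tests at 20 FPKM, the test of equal values and the count of splits were chosen before.

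The abundant J. coenia component TRINITY_DN40268, picked after its values were seen, is an example of a component whose rows moved in different ways. Whether its rows belong to one locus was not tested. Its row g2 was at 534 and 693 FPKM in wild-type forewings and at 202 and 137 FPKM in knockout forewings. Its row g3 was listed at 0 in all 4 wild types and at 173 to 242 FPKM in all 4 knockouts, and its row g1 was above 0 in wild-type hindwings alone, at 62.2 and 53.5 FPKM.

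In J. coenia 119 rows were listed at 0 in all 4 libraries of one genotype and at 5 FPKM or more in all 4 of the other, 76 in the knockouts and 43 in the wild types. The other 2 splits that keep wings of one genotype and number together gave 26 and 8. A candidate explanation is that sequence variants split one locus over several assembly rows. Rows of the same component that moved the opposite way by more than 1 (log2) accompanied 46.1% of the knockout-only rows, against 30.3% (the central 95% from 22.4% to 39.5%) in 1000 matched sets of uncalled rows, and 41.9% of the wild-type-only rows, against 14% (7% to 23.3%). The shallower depth of the wild types does not explain the 43 wild-type-only rows, which are listed at 0 in the deeper libraries. The other splits gave at most 13 rows in one direction. For the knockout-only rows depth and genotype cannot be told apart, because 15.8% of them had at least 20 FPKM in every knockout, between the bounds set in advance. A change of expression at the locus also stays open and was not tested, since it is unknown whether a component is one locus. The median change of the component sums, which include these rows, was 0.84 (log2) for knockout-only and -1.49 for wild-type-only rows. Per row it was 3.80 and -4.08. For rows that shared their component with others, the component medians were 0.77 and -0.37. Alone in their component were 18 of the wild-type-only rows and 4 of the knockout-only rows.

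In V. cardui the difference between the mosaic wings followed the knockout effect across rows. Rows called lower had a median difference of -0.86, below the range of -0.29 to 0.03 of random lists, and rows called higher had 0.04, inside their range of -0.24 to 0.09. The lists were not tested against each other. The correlation was 0.29 over all rows and 0.48 across rows with a mean of at least 20 FPKM. It is thus not confined to low rows, which by the bound set in advance went against depth. The rise itself does not exclude depth, since the largest correlation with a difference between replicates also rose, from 0.15 to 0.26. Composition was not tested: the 10 most abundant rows held 39.4% of total FPKM in the large-defect wing and 35.8% in the small-defect wing. The medians of the called rows were not tested for depth, and the large-defect wing was the shallower library. An axis along which libraries of one genotype also differ cannot be told apart from an effect of optix: the largest correlation with a difference between 2 libraries of one group was 0.26 at 20 FPKM and 0.15 over all rows, which is not far enough below 0.48 and 0.29 to exclude it, and only 3 such differences exist. The biological explanation, that more knockout tissue in the large-defect wing moved it toward the knockouts, may hold and was not tested apart from this correlation.

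Of the 54 V. cardui rows called lower, 42 were listed at 0 in both knockout forewings, and 33 of these also in both knockout hindwings. A possible explanation is few reads on short rows in the shallower knockouts. Values equal to that of another row in the same wild-type library occurred for 97.6% of the 42 rows and for 0% of values moved by 0.017, an excess of 97.6 points, but also for 90.4% of 5975 rows in the same range that were above 0 in both knockouts. The test therefore does not separate these rows from others, and few reads and lower expression cannot be told apart. In the mosaic individual 31 of the 42 were above 0 in the small-defect wing and 18 in the large-defect wing.

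For the mean of both J. coenia wings, 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, called as many rows (980 with wing as a term, against 220 in the highest other split). The highest other split put the libraries numbered 1 against those numbered 2, which points to a structure of the samples. Only 3 splits keep the wings of one genotype and number together (980, 220 and 7 calls), too few for a share under 0.05. At an unadjusted p under 0.05 (limma) the real split had 5382 rows and the split by number 4547. Wings of one genotype and number deviate together, so the 8 libraries are not independent, and the count of splits cannot exclude chance.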
